A study of Homo sapiens with 4 samples.

How the data were processed

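Total RNA from 4 samples of human neuroendocrine tumour cells was measured on 4 one-colour Affymetrix arrays, 1 array per sample. The cell lines were QGP1, described by the labels as a pancreatic neuroendocrine tumour line, and NCI-H727, a bronchial neuroendocrine tumour line. Per the labels' protocols, each line was electroporated with siRNA against DAXX (DAXX-KD) or with a negative control siRNA at a final 50 nM, and RNA was amplified and biotin-labelled with a 3' IVT kit. The labels name 2 DAXX siRNAs and do not say whether they were pooled. Groups were taken from the sample titles, which give 1 control and 1 DAXX-KD array per line. The source field of both NCI-H727 samples names QGP1 and the description field of all 4 samples reads ALDH high QGP1 cells, so the line names used here rest on the titles. Whether the cells were selected for high aldehyde dehydrogenase activity (ALDH high) before the arrays is not stated in the titles.

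The deposited table held log2 expression values made by the authors with RMA (affy 1.40.0, R 3.0.3, per the submitters' processing notes). RMA subtracts background, quantile-normalizes the arrays and summarises the probes of each probe set on the log2 scale. The table had 54613 probe sets and 0 Affymetrix control probe sets. Quantile normalization gives every array nearly the same distribution of values, so a shift shared by most genes of an array would be removed, and values are relative to the other genes of the array. Signal of dim probe sets lies close to background, where RMA compresses fold differences.

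Probe sets were named from the platform annotation given for the table. 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none; those with several or none were left out. The Entrez identifiers of 41037 probe sets were found in the RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 symbols needed an update. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 19775 genes. Genes with a mean under the 40th percentile of all probe sets (4.85 on the log2 scale) were left out, leaving 14648 genes. Some genes of the lists below were not measured past this filter or are not reported here.

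With 1 array per group in each line there was no replicate, so per line the log2 difference DAXX-KD minus control was described by size only, with genes counted at 2-fold or more and no p-value. The spread between probe sets of the same gene within a line is given as a yardstick for how far probe sets disagree. It comes from the same arrays and holds no error between arrays or cultures. The number of arrays limits the precision. The 2 lines were the only repeats of the knockdown, and a joint limma fit (limma 3.58.1, R 4.3.3) of treatment with cell line as a block used all 4 arrays, with 1 residual degree of freedom plus a prior of 4.18 degrees of freedom, two-sided moderated tests and Benjamini-Hochberg adjustment at 0.05. Its p-values measure how far the lines' differences vary around their mean; nothing in the labels says that any array came from a repeated culture. The coefficient for cell line in the same fit compared NCI-H727 with QGP1, with 2 arrays per line that differ in treatment. In simulated data with the same design and 14648 genes, this fit called 45 of 100 genes with a log2 change of 1 and 98 of 100 with a log2 change of 2, and 11.7% of the genes it called were unchanged ones, above the nominal 5%. This was 1 simulated draw, in which a changed gene changed alike in both lines, so the shares may differ in these arrays. Adjusted p-values of this fit were lenient in that draw and may be lenient here.

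30 gene lists were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives, except those said to be chosen later. They covered DAXX, histone H3.3 and H3K9 methylation; pancreatic neuroendocrine tumour genes; neuroendocrine, islet and bronchial markers; aldehyde dehydrogenases and stemness; the cell cycle; p53 targets; DNA repair; telomere maintenance; interferon and NF-kB responses; ATF4 and the unfolded protein response; heat shock; apoptosis; epithelial and mesenchymal genes; hypoxia and glycolysis; cholesterol and lipid synthesis; immediate early genes; Wnt and Notch targets; germline genes; imprinted genes; zinc finger genes; replication-dependent histones; ribosomal proteins; oxidative phosphorylation; housekeeping genes; fibroblast and endothelial, leukocyte, and pancreatic exocrine and ductal markers. For each list the median log2 difference per line was placed among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these arrays and is not a test across samples; in simulated data 20 of 20 lists of 25 genes shifted by 0.20 fell outside the 2.5th to 97.5th percentiles and 0 of 20 unshifted lists did. Adjusted p-values of the joint fit were also computed over each list alone.

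The text names DAXX, STC2 and the members of the DAXX list; per line the 10 genes with the largest difference in each direction past 2-fold; the 10 largest per direction shared by both lines; up to 10 per direction past the joint threshold; up to 4 members per list and line with the largest difference; the 10 largest line differences per direction with the 2-fold neuroendocrine, islet and bronchial markers; and the 5 largest differences between the lines' responses per direction. Genes without a characterised symbol, Y-linked genes and XIST were passed over. STC2 was put in the rule, and in the ATF4 list, with knowledge of the published study, so its own value is not independent evidence. Probe set identifiers ending in x_at or s_at can bind transcripts of several genes.

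Alternatives were the mean of a gene's probe sets, probe sets without the x_at and s_at suffixes, no filter, a 60th percentile filter, a second quantile normalization over the 4 arrays, intensity-dependent centring (lowess span 0.4), 1.5-fold and 3-fold thresholds, counting probe sets, characterised genes alone, limma with an intensity trend or robust prior, and the joint fit without the block. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.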

Results

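Gene expression was profiled in 2 human neuroendocrine tumour cell lines after siRNA against DAXX, the chaperone that places histone variant H3.3 at telomeres and silent chromatin together with ATRX. The series asked which genes depend on DAXX in pancreatic neuroendocrine tumour cells. QGP1 and NCI-H727 each gave 1 control and 1 DAXX-KD array, 4 arrays in all, with no replicate within a line. The RMA values of the arrays had medians from 5.31 to 5.36 on the log2 scale. Across genes, control and DAXX-KD arrays correlated at 0.995 in QGP1 and 0.992 in NCI-H727. In the text, differences are DAXX-KD minus control on the log2 scale, with the linear fold beside the main ones.

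The DAXX signal was lower in the DAXX-KD array of both lines. In QGP1 it went from 8.52 to 6.56, a 3.90-fold lower level that left 25.7% of the control signal. In NCI-H727 it went from 7.35 to 6.14, 2.31-fold lower, leaving 43.3%. A second DAXX probe set was 4.41-fold lower in QGP1 and 1.78-fold lower in NCI-H727. Both probe sets carry suffixes that mark possible binding of other transcripts, and each value rests on 1 array per condition. Over both lines the joint limma fit gave a DAXX difference of -1.59 (SE 0.21, lower in 2 of 2 lines), with an adjusted p of 0.374 over all genes and 0.0123 adjusted over the list alone. A fit without cell line as a block was chosen after the data were seen. None of the 12 calls that the limma fit made over a list alone passed in it, DAXX included (SE 0.51). That fit counts the difference between lines as error, so here and below it does not show whether a knockdown difference repeated.

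**Figure D1:**
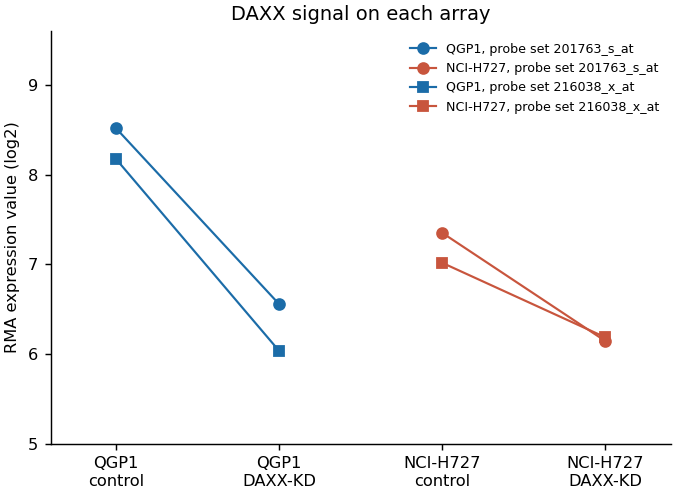
DAXX signal (RMA value, log2) on each of the 4 arrays, for the 2 DAXX probe sets (circles and squares); lines join the control and DAXX-KD arrays of a cell line. The main probe set goes from 8.52 to 6.56 in QGP1 and from 7.35 to 6.14 in NCI-H727.

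Partners of DAXX and the H3K9 methylation machinery differed by less than 2-fold. Of 23 measured members of this list, DAXX was the 1 member past 2-fold in each line, and the list medians were 0.02 in QGP1 (37.5th percentile of matched random lists) and -0.09 in NCI-H727 (11.7th percentile); in QGP1 the mean, -0.05, had the other sign. SP100, a component of PML nuclear bodies, where DAXX also resides, was 1.64-fold higher in QGP1 and 1.17-fold higher in NCI-H727. The other SP100 probe sets were higher in both lines too. ATRX differed by -0.15 in QGP1 and -0.60 in NCI-H727. Its other probe sets differed by -0.84 and -0.32 in NCI-H727 and by -0.06 and -0.07 in QGP1. The histone-binding protein DEK differed by -0.23 in QGP1 and -0.49 in NCI-H727, and the H3 chaperone ASF1A by 0.13 and 0.49. PML itself differed by -0.06 and -0.04. In the joint limma fit DAXX was the 1 member that passed adjusted over the list alone, and 0 members passed over all genes.

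In QGP1, genes of the amino acid and endoplasmic reticulum stress response led the higher side. DDIT4, an inhibitor of mTORC1, was 4.68-fold higher, and CHAC1, which degrades glutathione, was 4.13-fold higher. TRIB3, a pseudokinase induced by ATF4, was 2.90-fold higher, SESN2, a stress-induced regulator of mTORC1, 2.83-fold, and STC2, a secreted glycoprotein, 2.84-fold. SPX, the precursor of the peptide spexin, was 3.84-fold higher. INHBE, an activin subunit, went from 3.91, under the filter level of 4.85, to 5.62. The gastric trefoil peptide TFF1 was 2.60-fold higher and RUNDC3B 2.60-fold. DDX60L went from 3.25 to 4.58, both under the filter level, so no fold is given for it. In all, 38 genes were at least 2-fold higher and 34 at least 2-fold lower in DAXX-KD QGP1; leaving out genes with both QGP1 arrays under the filter level, chosen after the data were seen, gave 30 and 32.

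REG1A, a secreted protein of regenerating and inflamed pancreas, was the lowest gene in DAXX-KD QGP1 relative to control, at 9.49-fold lower. ODF2, a centriolar appendage protein, was 4.38-fold lower, and the activity-induced transcription factor EGR3 4.34-fold. NPAS4, of the same kind, went from 6.37 to 4.51, the last under the filter level. IGFBP5, a binding protein of insulin-like growth factors, was 3.66-fold lower, and all 6 of its probe sets past the filter were lower. The histone gene H2BC12L was 3.3-fold lower, ECI1, an isomerase of mitochondrial fatty acid oxidation, 3.28-fold, and the chemokine CXCL14 2.8-fold. The matrix protein FREM2 went from 4.70 to 2.95, both under the filter level. NKX2-2, an islet transcription factor, went from 4.80, under the filter level, to 5.93, and DDC, which makes serotonin and dopamine from their precursors, was 2.10-fold lower.

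Second probe sets bore on single genes of this comparison. STC2 and SESN2 were higher at both of their probe sets, the second at 1.41 and 1.42. The second probe set of TRIB3 differed by 0.16 and that of NPAS4 by -0.27. The H2BC12L probe set carries the x_at suffix and histone genes are near-identical, so that value is uncertain.

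The series' design text states 81 genes higher and 96 lower in DAXX-KD QGP1 past 2-fold after uncharacterised genes were left out. Here 35 characterised genes were higher and 33 lower. Counting each probe set of the table with no filter, those without a characterised gene included, gave 79 higher and 88 lower. Counting characterised genes by any probe set with no filter gave 64 higher and 61 lower. Both counts were chosen after the data were seen. The design text does not say which unit or filter was used. The probe sets of 1 gene disagreed with an SD of 0.202 in QGP1, and the central 95% of genes lay between -0.47 and 0.52.

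Genes lower in the DAXX-KD array made up most of the NCI-H727 comparison. ECI1 was 16.2-fold lower and GMPS, which makes GMP for nucleotide synthesis, 9.19-fold. MIEN1, a membrane-anchored protein linked to cell migration, was 5.67-fold lower, the receptor tyrosine kinase RET 5.38-fold, and ERRFI1, a feedback inhibitor of the EGF receptor, 5.3-fold. The scaffold IQGAP1 was 4.89-fold lower. ODF2 went from 7.32 to 4.42, the sialyltransferase ST8SIA4, which builds polysialic acid, from 6.10 to 3.77, FRMD5 from 6.64 to 4.25 and GDPD1 from 6.30 to 4.02; the DAXX-KD values of these 4 genes lay under the filter level, where differences are compressed, so no fold is given for them. In all, 194 genes were at least 2-fold lower and 26 at least 2-fold higher.

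The higher genes of NCI-H727 were led by NUP58, a nucleoporin, at 3.89-fold. PTGES, which makes prostaglandin E2, was 2.94-fold higher, the cell-surface protein LY6K 2.63-fold, SLC67A2 2.61-fold and the translation factor EIF5A2 2.45-fold. GAL, the neuropeptide galanin, was 2.44-fold higher, the matrix glycoprotein THBS1 2.39-fold, TMEM71 2.35-fold and the neuronal RNA-binding protein ELAVL2 2.34-fold. VWDE went from 2.22 to 3.48, both under the filter level, so no fold is given for it. ALDH1A3, a retinaldehyde dehydrogenase, was 3.42-fold lower, DLL3, an inhibitory Notch ligand of neuroendocrine cells, 2.28-fold lower, and RRM2B, a p53-induced ribonucleotide reductase subunit, 2.72-fold lower.

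The additional probe sets of GMPS (-2.59 and -1.06) and the 2 others of both IQGAP1 and ST8SIA4 were lower as well. The other 2 probe sets of RET differed by -0.10 and 0.07, the 3 others of NUP58 by -0.04 to 0.32, the 3 others of DLL3 by -0.21 to 0.25, and the second of PTGES by 0.12. The second probe sets of FRMD5 and GDPD1 differed by -0.26 and -0.12, the 3 others of THBS1 by 0.17 to 0.75, and the 2 others of SLC67A2 by 0.50 and 0.10. Probe sets of 1 gene disagreed with an SD of 0.275 in this line, and the central 95% of genes lay between -0.77 and 0.52.

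The lines shared more lower genes than independent lists would. 19 genes were at least 2-fold lower in both lines, against 0.450 for independent lists, and 1 was higher in both, against 0.067. The largest were ECI1 (-1.71 in QGP1 and -4.02 in NCI-H727), ODF2 (-2.13 and -2.90, the last to a value under the filter level), ERRFI1 (-1.35 and -2.40), PROSER1 (-1.35 and -2.19), MRPL45, a mitochondrial ribosome protein (-1.28 and -2.20), and FREM2 (-1.75 and -1.68, the first between QGP1 values under the filter level). MATN2, a matrix adaptor protein (-1.15 and -2.16), SCARB2, a lysosomal receptor (-1.30 and -1.92), ACADSB, an acyl-CoA dehydrogenase of branched amino acid breakdown (-1.04 and -2.01), and DAXX completed the 10 largest. NUP58 was the 1 shared higher gene (1.19 and 1.96); its 3 other probe sets differed by -0.25 to 0.08 in QGP1, and with the mean of a gene's probe sets 0 genes were shared higher.

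The other probe sets of ODF2 and PROSER1 were lower in both lines too, as were the 3 others of SCARB2, 1 of them by 0.1 or less, whereas the second probe set of ACADSB differed by 0.06 and 0.14. GBP1, an interferon-induced GTPase, was the 1 gene past 2-fold in opposite directions, at 1.17 in QGP1, between values under the filter level, and 2.13-fold lower in NCI-H727. Its other 2 probe sets differed by -0.34 and -0.52 in QGP1, so its QGP1 direction depends on the probe set. Across the 14648 genes, which are not independent replicates, the lines' differences correlated at Pearson 0.189 (bootstrap interval over genes 0.162 to 0.217) and Spearman 0.072, and 51.4% had the same sign.

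**Figure D2:**
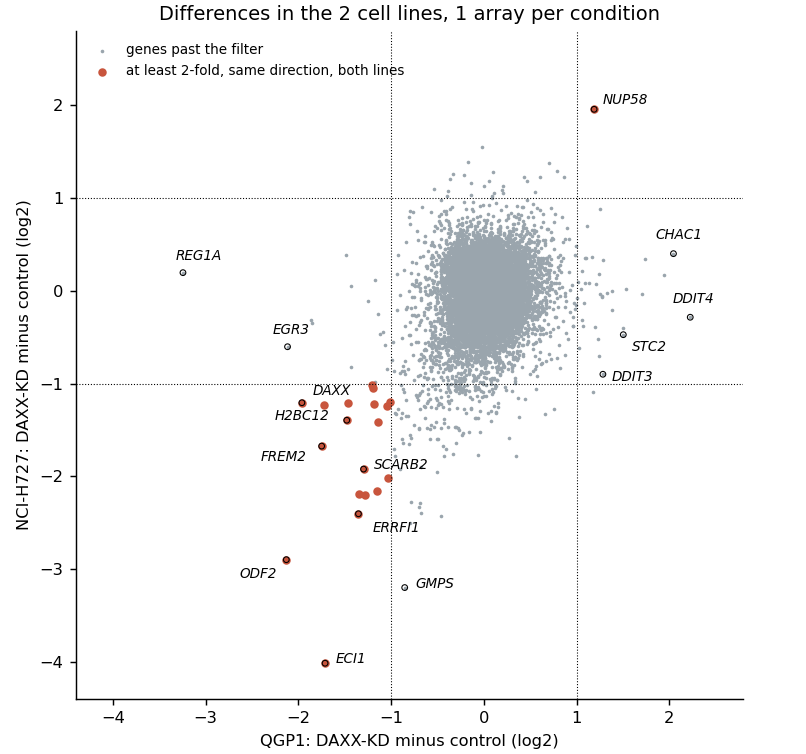
Log2 difference DAXX-KD minus control of each of 14648 genes in QGP1 (x axis) and NCI-H727 (y axis), 1 array per condition; dotted lines mark 2-fold. The 20 genes past 2-fold in the same direction in both lines are filled in red, 19 of them in the lower left corner; labelled genes are named in the text.

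The joint limma fit over both lines called 0 genes at adjusted p 0.05, with a smallest adjusted p of 0.374; at an unadjusted p under 0.05 there were 1014 genes, 410 higher and 604 lower in DAXX-KD. The 3 smallest unadjusted p-values in limma belonged to FREM2 (-1.71, SE 0.13, with QGP1 values under the filter level), ODF2 (-2.52, SE 0.21) and the histone gene H2BC12 (-1.44, SE 0.13), each with an adjusted p of 0.374. With an intensity trend in the limma prior, 5 genes passed, all lower in 2 of 2 lines: H2BC12 (adjusted p = 0.0102), ODF2 (0.03), SCARB2 (0.03), FREM2 (0.0396) and FABP5 (0.03). Without the block, chosen after the data were seen, 0 of these 5 passed in limma, with the same differences and SEs of 0.430 to 1.33 against 0.069 to 0.218. FABP5, a fatty acid binding protein, lies outside the naming rule and was chosen after its value (-0.84) was seen.

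The list median of ATF4 targets and unfolded protein response genes had opposite signs in the 2 lines, though single members did not all follow it. In QGP1 the 29 measured members had a median of 0.38, above all 10000 matched random lists (100th percentile), with 6 at least 2-fold higher, 11 at least 1.5-fold higher and 0 at least 1.5-fold lower. In NCI-H727 the median was -0.28, below the random lists (0th percentile), 24 of 29 were lower and 3 at least 1.5-fold lower. DDIT3, the stress transcription factor CHOP, was 2.43-fold higher in QGP1 and 1.87-fold lower in NCI-H727. ATF3 differed by 0.35 and -0.65 (its second probe set by 0.56 and -0.06), and STC2 by 1.5 and -0.47. XBP1 (-0.53 and -0.79) and the degradation factor SEL1L (-0.12 and -0.54) were lower in both.

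The second STC2 probe set differed by 0.17 in NCI-H727, against -0.47 at the first. The list medians kept their sign after a second quantile normalization (0.35 and -0.21) and without STC2 (0.37 and -0.25), both chosen after the data were seen. In the joint limma fit 0 members passed, over all genes or adjusted over the list alone.

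**Figure D3:**
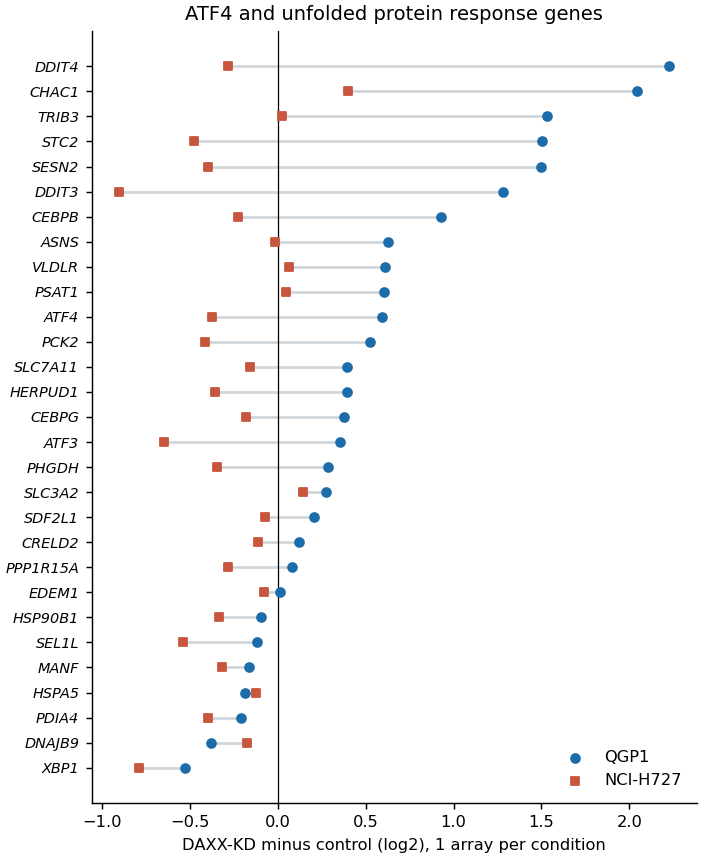
Log2 difference DAXX-KD minus control of the 29 ATF4 and unfolded protein response genes in QGP1 (circles) and NCI-H727 (squares), 1 array per condition. DDIT4, CHAC1, TRIB3, STC2, SESN2 and DDIT3 are past 2-fold higher in QGP1, and 24 of 29 genes are below 0 in NCI-H727.

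Immediate early genes, transcribed within minutes of growth factor signals, had a median of -0.15 in QGP1 (0th percentile) and 0.12 in NCI-H727 (99.1st percentile) over 22 members. Single members did not all follow the NCI-H727 median. FOS was 2.07-fold lower in QGP1 and 1.8-fold lower in NCI-H727, EGR3 was 1.52-fold lower and EGR1 1.55-fold lower in NCI-H727, while the ERK phosphatase DUSP5 was higher in both (0.49 and 0.62), as was PHLDA1 (0.99 and 0.48; 5 of 5 other probe sets higher in both). In the joint limma fit 0 members passed over all genes and 4 passed adjusted over the list alone: FOS (-0.95, adjusted p = 0.0168), DUSP5 (0.56, 0.04), PHLDA1 (0.74, 0.04) and CCN2 (-0.56, 0.04), the last outside the naming rule and chosen after its value was seen; none of the 4 passed without the block.

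The replication-dependent histone list was shifted to lower values in both lines, with 15 of 26 members below 0 and 10 above in QGP1 and 18 below and 8 above in NCI-H727. Over the 26 members the median was -0.12 in QGP1 (1.05th percentile) and -0.12 in NCI-H727 (0.32nd percentile), with 2 members in each line at least 2-fold lower and 0 higher. H2BC12 was 2.79-fold lower in QGP1 and 2.63-fold lower in NCI-H727, H2BC6 2.71-fold and 1.77-fold, H2AC6 1.69-fold and 2.73-fold, and H2BC9 1.95-fold and 1.83-fold. In the joint limma fit 0 passed over all genes and 5 fell adjusted over the list alone: H2BC12 (adjusted p = 0.00203), H2BC9 (0.00933), H2BC6 (0.0131), H2AC6 (0.0141) and H2BC5 (0.0141), the last outside the naming rule and chosen after its value was seen. These genes are near-identical copies whose probes can bind each other's transcripts, so the members are not separate measurements. Without x_at and s_at probe sets H2BC12 still passed in limma and the 4 others had no probe set left; without the block 0 of the 5 passed, H2BC12 with an SE of 0.83 against 0.13. Both were chosen after the data were seen. Without the expression filter the QGP1 list lay at the 14.7th percentile.

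Bronchial and lung neuroendocrine markers had a median of -0.21 in QGP1 (0.16th percentile) and -0.07 in NCI-H727 (13.1st percentile) over 13 members; with the mean of a gene's probe sets the QGP1 list lay at the 13.0th percentile and the NCI-H727 median was 0.01. GRP, the gastrin-releasing peptide of pulmonary neuroendocrine cells, was 2.06-fold lower in QGP1 and went from 5.37 to 4.12, under the filter level, in NCI-H727, and was the 1 member that fell in the joint limma fit adjusted over the list alone (-1.14, SE 0.13, adjusted p = 0.00396; SE 4.06 and not passed without the block), with 0 over all genes. NKX2-1, the lung and thyroid transcription factor, differed by -0.39 and -0.13. Neuroendocrine markers had medians of -0.06 in QGP1 (3.84th percentile, DDC the 1 of 22 past 2-fold; -0.11 and the 0.17th percentile with the mean of a gene's probe sets, 2.40th after intensity-dependent centring, 2.12th after the second quantile normalization) and -0.002 in NCI-H727 (31.7th percentile). Islet transcription factors and hormones had medians of -0.06 (13.8th percentile) and 0.12 (86.3rd percentile) over 13 members, with SST, somatostatin, 1.69-fold lower in QGP1; the QGP1 median was 0.05 (74.1st percentile) with the mean of a gene's probe sets and lay at the 54.2nd percentile with no filter. In limma 0 members of either list passed, also adjusted over the list alone.

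Proliferation genes had a median of 0.04 in QGP1 (67.8th percentile) and -0.11 in NCI-H727 (1.33rd percentile), with 0 of 35 past 2-fold. After a second quantile normalization, chosen after the data were seen, the NCI-H727 median was -0.05, at the 5.66th percentile. The NCI-H727 list lay at the 4.73rd percentile with the mean of a gene's probe sets and the 3.50th after intensity-dependent centring. CDK2 was 1.58-fold lower in NCI-H727 and the kinetochore motor CENPE 1.48-fold lower. MKI67 differed by -0.32 in NCI-H727, where its 3 other probe sets lay between -0.69 and -0.53. In QGP1 MKI67 differed by 0.30, with the 3 others between -0.06 and 0.02. Zinc finger genes, many of which encode repressors of repeated DNA, had a median of 0.02 in QGP1 (47.3rd percentile; -0.01 after intensity-dependent centring) and -0.10 in NCI-H727 (0th percentile), where 260 of 377 were lower, 6 at least 2-fold. The NCI-H727 median shrank to -0.04 after the second quantile normalization, still at the 0th percentile. ZNF702P was 2.48-fold and ZNF678 2.13-fold lower in NCI-H727, and ZNF217 was 2.10-fold higher in QGP1. Heat shock genes had medians of -0.07 (3.72nd percentile) and -0.10 (5.49th percentile); of 15, DNAJB4, a co-chaperone, was 1.90-fold lower in QGP1 and 2.41-fold lower in NCI-H727 and fell in limma adjusted over the list alone (-1.10, SE 0.15, adjusted p = 0.0088; SE 0.34 and not passed without the block). In limma 0 members of these 3 lists passed over all genes.

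**Figure D4:**
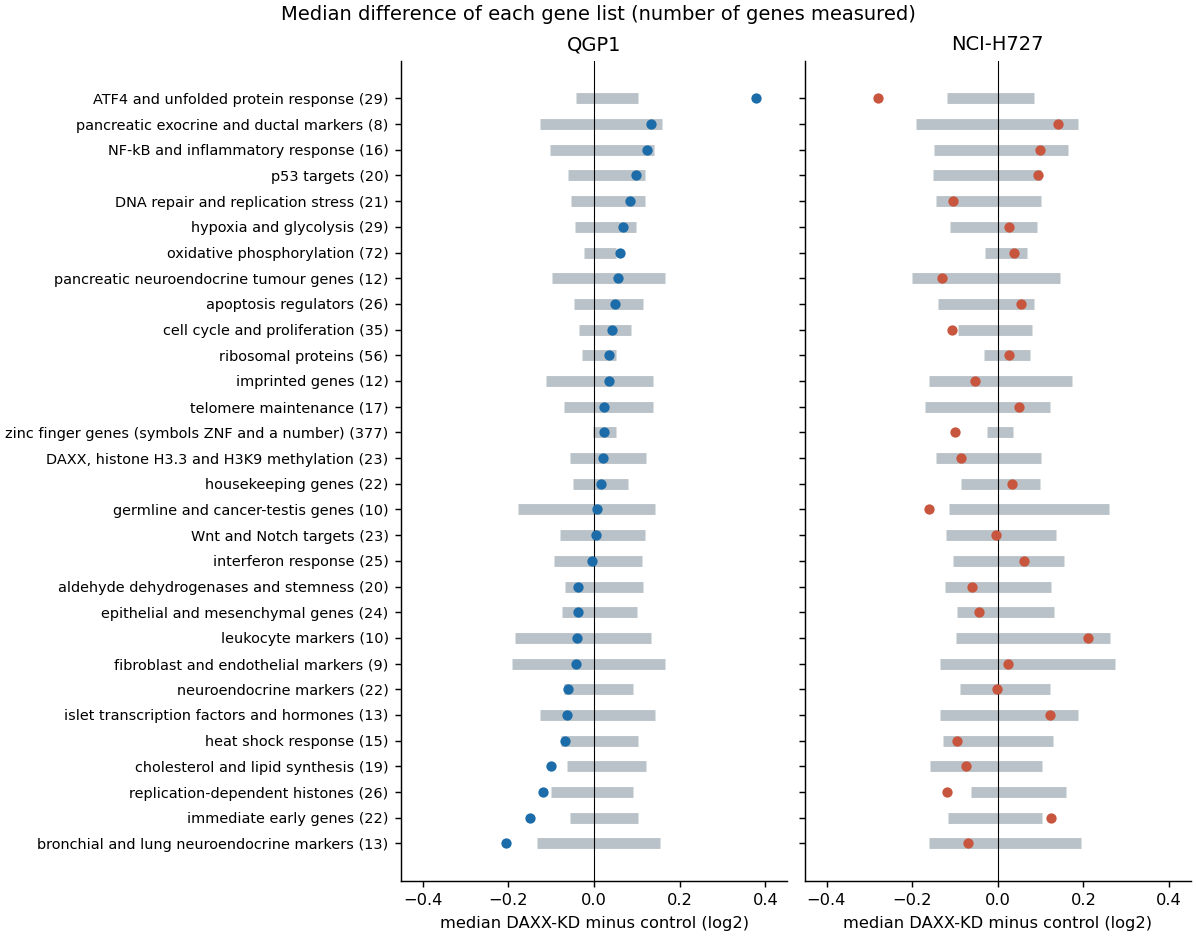
Median log2 difference DAXX-KD minus control of each of the 30 gene lists (dots) in QGP1 (left) and NCI-H727 (right), 1 array per condition; grey bars span the central 95% of 10000 expression-matched random lists. The ATF4 list lies at 0.38 in QGP1 and -0.28 in NCI-H727.

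The arrays titled NCI-H727 and QGP1 differed far more from each other than control from DAXX-KD. In the limma fit 3289 genes passed adjusted p 0.05 and 2-fold, 1560 higher in the arrays titled NCI-H727 and 1729 higher in those titled QGP1, with a smallest adjusted p of 1.77e-05. PRSS2, the digestive enzyme precursor trypsinogen, was 8.98 higher in NCI-H727 (SE 0.15) and the plasma protein AMBP 7.63. The imprinted gene MEST, the EGF receptor ligand EREG, the WNT antagonist DKK1, EMP1, ST6GAL2, ARHGAP6 and EPB41L3 were each over 7 higher. On the other side TPH1, which starts serotonin synthesis, IL13RA2, HS3ST3B1, the prostaglandin receptor PTGER4, the neuronal genes DCX and GAP43, the lung-expressed gene SFTA3, GUCY1B1, SH3BGRL and RGS4 were each over 7 higher in QGP1. Of the 10 largest differences per direction, 8 of those higher in NCI-H727 and 9 of those higher in QGP1 had both arrays of the other line under the filter level, where RMA compresses differences, so their exact sizes and order are not given.

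Of 13 measured bronchial and lung markers, 5 were higher in the arrays titled QGP1, the line described as pancreatic, 1 was higher in those titled NCI-H727, 1 passed the test under 2-fold and 6 did not pass, with a list median of 0.04 (NCI-H727 minus QGP1). NKX2-1 and GRP, with 1 or both NCI-H727 arrays under the filter level, the calcitonin-related CALCB (-3.63), FOXA1 (-1.30) and FOXJ1 (-1.05) were higher in the arrays titled QGP1, and MUC5AC (1.5) was higher in those titled NCI-H727, while SFTPB (0.04) and KRT5 (0.15) did not pass. Of 13 islet genes, of which 5 did not pass, RFX6 and NKX2-2, with 1 or both QGP1 arrays under the filter level, TTR (2.51) and GATA6 (1.90) were higher in the arrays titled NCI-H727, and SST (-1.62) and PAX6 (-1.31) in those titled QGP1. Of 22 general neuroendocrine markers, of which 10 did not pass, UCHL1 (4.27) and CHGA (1.06) were higher in NCI-H727, and SCG5 (-6.40), NCAM1 (-2.64), PAM (-1.31), ENO2 (-1.24) and PCSK1N (-1.20) in QGP1. All genes given here as higher passed adjusted p 0.05 in limma, with 2 arrays per line. Titles and source fields disagree for the NCI-H727 samples, so each direction between lines rests on the titles, while DAXX-KD and control are compared within a pair. The lung genes NKX2-1, GRP, SFTA3 and CALCB were higher in the arrays titled QGP1, and RFX6, NKX2-2, TTR and PRSS2 in those titled NCI-H727, the reverse of what the names would give. Not all markers went this way. Of the 8 measured exocrine and ductal markers, PRSS2 among them, 3 were at least 2-fold higher in the arrays titled NCI-H727 and 2 in those titled QGP1. An exchange of the line names between the pairs was not tested, since no reference profile of either line was compared, and stays open. It would assign each knockdown response, and the comparison with the 81 and 96 genes of the design text, to the other line.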

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

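Each item here is a difference between the responses of the 2 lines in opposite directions; with 1 array per condition none of these differences was tested. The tests weighed here were written before their results were seen, except the second quantile normalization and the list without STC2 in the report. DDIT3, which encodes CHOP, differed between QGP1 and NCI-H727 by 2.18 on the log2 scale (1.28 against -0.90). For the neutrophil chemokine CXCL2 the gap was 1.52 (0.79 against -0.73). ZNF804A showed a gap of 1.66 (0.82 against -0.84, the latter between values under the filter level). LPL, lipoprotein lipase, went the other way with -1.61 (-0.77 against 0.85, from a value under the filter level), as did the axon guidance receptor PLXNA4 with -1.65 (-0.79, to a value under the filter level, against 0.86), although the 2 other PLXNA4 probe sets were at -0.13 and -0.06 in QGP1. GBP1 had a gap of 2.27 (1.17 against -1.09), which its other probe sets did not show and whose QGP1 values lay under the filter level. The median gap of the immediate early genes was -0.150, at the 0.15th percentile of matched random lists. The medians were opposite, but FOS, FOSB, EGR1 and EGR3 were lower, and DUSP5 and PHLDA1 higher, in both lines. In NCI-H727 4 members of this list were at least 1.5-fold lower and 1 at least 1.5-fold higher, with a list mean of 0.01.

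The ATF4 and unfolded protein response list had a median gap of 0.554 between the lines, at the 100th percentile of matched random lists. Intensity-dependent bias or scaling between arrays would have shown as a gap largely removed by intensity-dependent centring; it was 0.533 after centring, still at the 100th percentile, which argues against such bias as the whole cause. The state of single cultures rather than DAXX stays open, because there was 1 array per group and no further culture to show whether the direction repeats. A line-dependent stress response to the loss of DAXX remains as an untested biological hypothesis.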

How the results depend on the processing

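The DAXX difference kept its sign and size under each alternative that could be run; without x_at and s_at probe sets DAXX had no probe set left and gave no value. Counts of genes depended on the unit and threshold. In QGP1 the 72 genes past 2-fold became 44 with the mean of a gene's probe sets, 449 at 1.5-fold, 14 at 3-fold and 126 as probe sets. Chosen after the data were seen, QGP1 gave 167 probe sets with no filter and 125 characterised genes by any probe set. Asking for 1 array of the line at the filter level, also chosen later, gave 62 genes in QGP1, 216 in NCI-H727 and 19 shared. In NCI-H727 the 220 genes became 119, 961, 37 and 567 in the same order, and 632 and 447 under the later choices. The 20 genes shared in direction became 13, 123, 3 and 37. By construction these settings count other units or thresholds; for the mean of probe sets the cause was not tested. The Pearson correlation between lines of 0.189 was 0.127 with no filter, 0.280 with the 60th percentile filter and 0.223 after centring, the cause was not tested. The joint limma fit called 5 genes with an intensity trend and 0 under its other alternatives, including the fit with no replicate block, where treatment stood alone. The calls adjusted over a list alone depended on the pairing by line: chosen after the data were seen, the fit without the block kept 0 of 12, with the same differences but SEs of 0.323 to 4.06 against 0.127 to 0.209, since the difference between lines then counted as error. The 5 calls with an intensity trend also became 0 without the block (SEs 0.430 to 1.33 against 0.069 to 0.218). With the trend 23 genes passed over a list alone, the 12 among them. The other alternatives gave 9 to 17, with 7 of the 12 kept without x_at and s_at probe sets and 12 under each other one. For these calls the trend, the robust prior and the 60th percentile filter were chosen after the data were seen. So were the second quantile normalization and the setting without x_at and s_at probe sets. Leaving out either line left no residual degrees of freedom and so gave differences without a test. The germline list median in NCI-H727 turned from -0.16 to 0.034 with no filter, where more dim genes entered, and GBP1 in QGP1 turned from 1.17 to -0.34 without x_at and s_at probe sets, since another probe set then stood for the gene. Of 242 list medians under alternatives, 206 moved by less than the spread of matched random lists and 35 by more; 214 kept their sign and 28 did not. Of the named gene values, 3220 moved by less than the probe set spread and 399 by more. Low signal over background limits dim genes, whose differences RMA compresses.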

Other observations

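The tests of a graded response, of siRNAs acting on other transcripts and of a faulty probe set in every shared gene, reported here, were chosen after the results were seen. Cholesterol and lipid synthesis genes had a median of -0.10 in QGP1 (0.355th percentile) and -0.07 in NCI-H727 (19.7th percentile); squalene epoxidase SQLE differed by -0.46 in QGP1 (its 3 others by -0.23 to 0.06), and STARD4, a cholesterol carrier, by -0.31 and -0.64. Oxidative phosphorylation genes lay slightly above 0 in QGP1 (0.06, 99.5th percentile; 67.2nd with the mean of a gene's probe sets) and at 0.04 in NCI-H727 (79.2nd percentile). Hypoxia and glycolysis genes had medians of 0.07 (85.9th percentile) and 0.03 (71.4th percentile, mean -0.03), and VEGFA was 1.74-fold higher in QGP1. In NCI-H727 STC1 was 1.89-fold higher (its 2 other probe sets at 0.15 and 0.38). The glucose transporter SLC2A3 was at -0.97 in NCI-H727, to a value under the filter level, though its other 2 probe sets were at 0.32 and 0.18. Germline and cancer-testis genes had medians of 0.01 (64.9th percentile) and -0.16 (0.89th percentile) over 10 members, with CTAG2 at 0.80, from a value under the filter level, and -0.39; without the expression filter the NCI-H727 median was 0.03, and with the mean of a gene's probe sets it lay at the 10.6th percentile and the QGP1 median was -0.16. Stemness genes and aldehyde dehydrogenases had medians of -0.04 (10.1st percentile, mean 0.03) and -0.06 (13.7th percentile). The receptor KIT was 1.61-fold higher in QGP1 and at 0.67 in NCI-H727, from a control value under the filter level. In NCI-H727 2 members of this list were at least 1.5-fold lower, ALDH1A3 (-1.77) and ALDH1A1 (-0.69), and 1 at least 1.5-fold higher. The descriptions call all 4 samples ALDH high, so this list may describe selected cells in control and DAXX-KD alike. Its QGP1 median was 0.006 after intensity-dependent centring.

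The following lists lay within the range of random lists in both lines by the brightest probe set of each gene; with the mean of a gene's probe sets NF-kB targets (98.1st percentile) and apoptosis regulators (98.0th percentile) lay above it in NCI-H727. p53 targets had medians of 0.10 (93.6th percentile) and 0.09 (96.4th percentile; mean -0.06), with GADD45A 1.78-fold higher in QGP1. DNA repair genes were at 0.09 (88.7th percentile) and -0.11 (7.46th percentile), and telomere maintenance at 0.02 (43.2nd percentile) and 0.05 (80.7th percentile, mean -0.01). Pancreatic neuroendocrine tumour genes were at 0.06 (64.4th percentile) and -0.13 (10.1st percentile). After a second quantile normalization, chosen after the data were seen, the DNA repair and tumour gene medians in NCI-H727 were -0.06 and -0.04. Interferon genes were at -0.005 (38.8th percentile; mean 0.06) and 0.06 (69.2nd percentile; -0.02 with the mean of probe sets), with the RNA sensor IFIH1 at 0.70 in QGP1; NF-kB targets at 0.12 (96.0th percentile) and 0.10 (85.1st percentile); apoptosis regulators at 0.05 (63.7th percentile) and 0.05 (91.1st percentile), with PMAIP1, the cell death protein NOXA, 1.45-fold and 1.91-fold higher. Epithelial and mesenchymal genes were at -0.04 (13.3rd percentile) and -0.04 (12.2nd percentile), with SNAI2 at -0.74 in NCI-H727, and VIM, vimentin, 1.93-fold higher in NCI-H727. Wnt and Notch targets were at 0.004 (39.3rd percentile, -0.009 without the filter) and -0.005 (38.0th percentile, -0.008 without the filter). Imprinted genes were at 0.04 (63.4th percentile) and -0.05 (19.4th percentile), with the other sign in each line without the filter. Ribosomal proteins were at 0.04 (87.2nd percentile) and 0.03 (62.8th percentile; -0.01 after intensity-dependent centring) and housekeeping genes at 0.02 (50.2nd percentile) and 0.03 (71.6th percentile). Markers of other cell types were at -0.04 (42.5th percentile; mean 0.09) and 0.02 (26.6th percentile) for fibroblasts and endothelium, -0.04 (47.1st percentile) and 0.21 (91.5th percentile) for leukocytes, and 0.13 (95.5th percentile; -0.004 without the filter) and 0.14 (92.5th percentile) for exocrine and ductal pancreas. The joint limma fit called 0 members of the lists in this and the preceding paragraph, over all genes or adjusted over the list alone.

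Of 18 genes besides DAXX at least 2-fold lower in both lines, 15 were lowered more than DAXX in NCI-H727 and 1, ODF2, in QGP1. A single faulty or cross-hybridising probe set per gene was weighed by 13 other probe sets of 7 of these genes: 46.2% of them were at least 1.5-fold lower in both lines and 10 of 13 were lower in both. A share under 50% had been written beforehand as the outcome for this explanation, but 13 probe sets are too few to tell the share from 50%, so it stays open for the genes as a set. The 6 that were at least 1.5-fold lower, against 0.089 expected from all probe sets past the filter, argue against a faulty probe set in every one of these genes. They belong to ODF2, PROSER1, SCARB2 and the noncoding RNA MIAT, the last outside the naming rule and chosen after its values were seen; for the other genes it stays open. A response graded by the depth of the DAXX knockdown would lower the genes less in NCI-H727, where DAXX was lowered less. The median NCI-H727 minus QGP1 difference was -0.237, with a bootstrap interval over the 18 genes of -0.882 to 0.079, which includes 0. That interval holds no variation between cultures. The 18 genes were also picked by these same differences, and more genes were at least 2-fold lower in NCI-H727 (194) than in QGP1 (34). The median therefore cannot decide the question, and a graded response stays open. siRNAs acting on transcripts other than DAXX also stay open: 95% of the genes shared in direction were lower, but siRNA sequences were not analysed here. The labels name 2 DAXX siRNAs and do not say whether they were pooled, so use of the same siRNA in both lines is not established. A shared response to the loss of DAXX is the biological alternative that the design names and cannot be told apart from such siRNA effects with these arrays.

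Of the genes past 2-fold in NCI-H727, 88.2% were lower. Had intensity-dependent bias or scaling made this excess, centring would have evened it out. After intensity-dependent centring 87.7% were lower, and 83.3% after a second quantile normalization. Centring moves the middle of the differences at each intensity and leaves their spread, so it does not bear on unequal spread. A fault of the NCI-H727 DAXX-KD array alone would leave the same genes unremarkable in QGP1; their QGP1 median was -0.390, below the range of -0.005 to 0.063 for matched random lists, with 163 of 194 lower there, and -0.353 over the 175 genes left after removing the 19 shared ones. The centred share argues against a shift between arrays as the whole cause. The QGP1 values argue against a fault of the NCI-H727 DAXX-KD array alone as the whole cause. The 26 higher genes had a QGP1 median of 0.10, at the 95.8th percentile. The siRNAs and the loss of DAXX stay open as candidate sources of the lower genes in both lines.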
